A study of Mus musculus with 2 samples.

How the data were processed

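RNA from mouse primary hepatocytes (liver parenchymal cells isolated for culture) was measured on 2 microarrays, 1 from cells given control siRNA and 1 from cells given G0s2 siRNA. Per the labels' protocols, cells in 24-well plates in medium with 10% serum received 50 pmol of siRNA with a lipid transfection reagent. RNA was taken 24 hours later, and 0.5 ug was amplified and labelled with Cy3 in a 1-colour design. Each group was assigned from its sample label. Per the file headers, both arrays lay on the same slide and shared a scan start, so position on the slide and group cannot be told apart and no slide block could be fitted.

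The deposited scanner tables hold, per the file headers, spot intensity values read with Agilent Feature Extraction 10.7.1.1. The submitters' processing notes name the same program. The processed signal is a linear intensity after the scanner's background correction, per the file headers. The deposited series table holds 39429 rows, and 97.8% of its ranked values were identical in both columns, each with a median of 33.1. Its columns correlated with the scanner's processed signals across probes at Spearman rho of at least 0.999914. The intensity values of the authors' series table were therefore handled as linear and normalized to a common distribution, although the method is not given in the sources used here. They entered only as an alternative.

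The main values were log2 processed signals minus each array's 75th percentile. Control spots and spots flagged as outliers were left out, which removed 5 probes, and spots of a probe were averaged. The control array had 2 non-uniform and 277 population outlier spots, and the G0s2 siRNA array had 4 and 200. No spot was saturated. Signal at the 75th percentile was 418 on the control array and 728 on the G0s2 siRNA array. The share of probes well above background was 54.1% and 58.2%. Of 153 negative control spots per array, 0 and 1 were well above background.

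Of 39424 probes kept, 26408 were named by accession through a RefSeq gene table of assembly GRCm38.p6, 3854 by symbol and 734 by synonym, and 8428 had no current symbol. That table served only for names and for the order of neighbouring genes. Probe coordinates are those of the scanner tables on mm9. Each gene was represented by its brightest probe well above background on at least 1 array. This left 15419 genes, of which 14120 were well above background on both arrays, 1040 were not on the control array and 259 were not on the G0s2 siRNA array. Where a gene was dim on 1 array, that array's value was set to the higher of its own signal and the lowest well-above-background signal. Its difference is a bound, written as at least N-fold.

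With 1 array per group there was no replicate check, and no p-value was computed. Every difference compares 2 arrays, not conditions. The error given is the scanner's own signal error propagated to the log2 difference, with a median of 0.20 over genes measured on both arrays. It leaves out variation between cultures, RNA extracts and labellings. The number of arrays limits the precision.

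Genes were counted at a log2 difference of at least 1 in either direction. Before the data were examined, 41 gene lists were fixed with 684 genes, 616 of which were measured. The median difference of each list was set against 10000 random lists of the same size matched on mean level in 20 bins. A list stood apart below percentile 2.5 or above percentile 97.5, as a description of these arrays. At that rule about 2.05 of 41 lists would stand apart if genes varied independently, since random lists were drawn gene by gene. Genes of 1 list can vary together and some lists share members, so more lists can stand apart without any effect of the siRNA. The rule for named genes was also fixed then. It took G0s2, the 12 largest increases and 12 largest decreases among genes with an official-style symbol measured on both arrays, the 4 largest bounds each way, and up to 4 members with the largest difference per list, plus members needed to describe a list. Some members that this rule allows are not reported here.

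Other settings chosen at the same stage were normexp background correction with an offset of 50, centring on the median of probes above background, quantile and loess normalization, centring on spike-in controls, other filters on dim probes, the mean over probes, leaving out saturated spots, the authors' processed values, rules of 1.5-fold and 3-fold, and a rule of more than 2 times the scanner error. Chosen after seeing the data were removal of a lowess trend (span 0.3) with probe position and GC content, random lists matched on probe position, and a count restricted to genes with several probes. Intervals on medians of lists and probe pairs came from 10000 bootstrap draws over genes or pairs. They describe genes, which are not replicates.

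Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9 for plots. The comparison of G0s2 siRNA with control siRNA was tested on simulated data of 14382 genes built from the control array. All 100 genes changed 4-fold were recovered (100%), and scanner error alone carried 11 of 14162 unchanged genes past the 2-fold rule. A simulated list shifted upward reached percentile 100 and an unshifted list percentile 13.6. The simulated arrays shared signals and detection flags and differed only by scanner error, a brightness offset and the set shifts. The simulation therefore checks the calculation. It does not estimate how many real calls are false, nor test lists whose genes vary together.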

Results

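The series addressed how knockdown of G0s2 affects gene expression in mouse primary hepatocytes. G0s2 encodes an inhibitor of adipose triglyceride lipase, the enzyme encoded by Pnpla2 that starts triglyceride breakdown. One array was made from cells given control siRNA and 1 from cells given G0s2 siRNA, 24 hours after transfection. Levels are log2 signals relative to each array's 75th percentile, and differences are G0s2 siRNA minus control siRNA. Each group has 1 array, so no difference has a replicate check, and the error given is the scanner's own.

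G0s2 itself was lower with G0s2 siRNA, by 6.50-fold. Its level was -0.13 on the control array and -2.83 on the G0s2 siRNA array, a difference of -2.70 ± 0.21, and it was well above background on both. The probe, A_52_P681391 for NM_008059, lies on chromosome 1 from 195098925 to 195098984 of mm9 on the minus strand, at position 212 of the transcript. Its 60 bases are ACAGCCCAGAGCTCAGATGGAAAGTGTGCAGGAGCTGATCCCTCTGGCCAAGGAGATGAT. Exon and UTR annotation on that build was not used here, and the siRNA target site is not given in the sources used here. Under spike-in centring the difference was -1.28.

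Among 15419 genes, 742 were at least 2-fold higher and 842 at least 2-fold lower with G0s2 siRNA. Of these, 77 were at least 4-fold higher and 108 at least 4-fold lower. Across the genes measured on both arrays, levels correlated at Pearson r = 0.979 and Spearman rho = 0.977, across genes that are not independent replicates. Higher genes made up 46.8% of those past the rule. That share was 81.5% when arrays were centred on the median of probes above background and 99.6% with spike-in centring, so directions here are relative to the array's 75th percentile. The spike-in probes used differed by -0.08 to -0.98 while the 75th percentile of signal was 418 on the control and 728 on the G0s2 siRNA array. The stated amount of RNA labelled was 0.5 ug for both arrays. Whether spike-in amounts or the amounts put on the arrays differed is not given in the sources used here, so the spike-in values have no settled scale. Among genes with several probes, the next brightest probe also passed the rule in 64 of 128 higher and 63 of 119 lower genes.

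**Figure D1:**
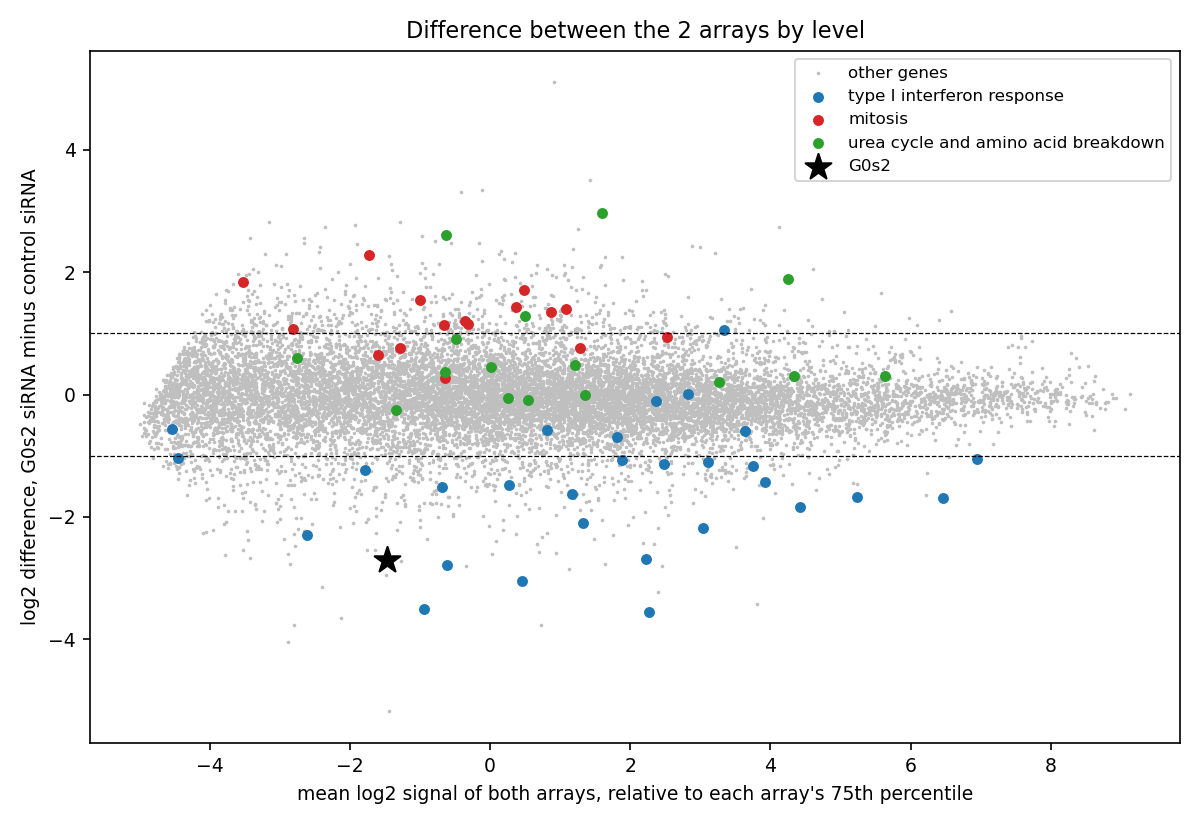
Each point is a gene well above background on both arrays, with its mean log2 level on the horizontal axis and its log2 difference, G0s2 siRNA minus control siRNA, on the vertical axis. Dashed lines mark the 2-fold rule, coloured points are members of 3 fixed lists, and the star marks G0s2 at -2.70.

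Of the 12 largest decreases, 3 were in members of the fixed type I interferon list, Ifit3 at -3.55, Oas2 at -3.51 and Ifi44 at -3.04. Sftpd, which encodes the collectin surfactant protein D, had the lowest difference at -5.18 ± 0.24, 36.2-fold lower, and its other probe gave -3.81. Mest, an imprinted gene, differed by -4.05 ± 0.32, and its other probe by -2.94. Outside the list, Ifit3b differed by -3.77, Tgtp2, which encodes a GTPase, by -3.43 and the nucleic acid sensor gene Zbp1 by -3.22. Ifit3 and Ifit3b are near-identical copies, as are Tgtp2 and its neighbour Tgtp1, so their separate values are uncertain, and a further Tgtp2 probe gave -1.32. Tekt5, of the tektin family, differed by -3.76. The kinase gene Pak3 differed by -3.65, the actin-binding protein gene Nexn by -3.15 and Id1, an inhibitor of DNA binding, by -2.94. Apart from Mest, each of these decreases rests on 1 spot per array. Under normexp several were smaller by over 1.5 times in fold, with Sftpd at -3.83, Pak3 at -2.55, Mest at -2.39, Tekt5 at -2.25, Id1 at -2.22 and Nexn at -2.08.

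The largest increase was that of Cited1, a transcriptional coactivator gene, at 5.10 ± 0.21, or 34.4-fold. Proz, which encodes the plasma protein Z, differed by 3.51, although its other probe gave 1.06. The G protein subunit gene Gna11 differed by 3.34 and Suclg2, of succinyl-CoA ligase, by 3.32. Cps1, the entry enzyme of the urea cycle, differed by 2.96 and Sds, serine dehydratase, by 2.60. The others were the mitochondrial carrier gene Slc25a30 at 2.83, the scaffold gene Homer2 at 2.82, the exocyst gene Exoc4 at 2.78, the anion channel gene Lrrc8a at 2.74, the cationic amino acid transporter gene Slc7a2 at 2.73 and the actin regulator gene Arpc1a at 2.71. The other probe of Exoc4 gave 0.34 and that of Lrrc8a 1.79. Each of these increases rests on 1 spot per array, and genes here other than Proz, Exoc4 and Lrrc8a had no other measured probe. Under normexp Slc25a30 differed by 1.95, Exoc4 by 1.83, Slc7a2 by 1.39 and Homer2 by 1.12.

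Some genes were well above background on 1 array only. Plekhs1 was at least 11.7-fold lower with G0s2 siRNA, the Schlafen family gene Slfn8 at least 8.06-fold, Rbmy at least 7.86-fold and the chemokine gene Cxcl5 at least 7.82-fold. Rbmy has near-identical copies on the Y chromosome and is uncertain. Its other probe was well above background on the G0s2 siRNA array only and gave no fold, and the mean over its probes was -1.49. Col8a2, a collagen gene, was at least 19.4-fold higher, Odf4 at least 13.9-fold, the olfactory receptor gene Olfr1471 at least 12.1-fold and B3gat2 at least 9.11-fold. Each rests on 1 spot per array, and each bound depends on the background correction. Under normexp the differences were -1.93 for Plekhs1, -1.43 for Slfn8, -1.62 for Rbmy, -1.64 for Cxcl5, 2.21 for Col8a2, 1.82 for Odf4, 1.70 for Olfr1471 and 1.41 for B3gat2.

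Interferon response genes were lower as a group with G0s2 siRNA. In the type I interferon list, 22 of 29 measured members were at least 2-fold lower, 1 was at least 2-fold higher and the median difference was -1.44, below all random lists matched on level. Mx1, an antiviral GTPase gene, differed by -2.78, Oasl2 by -2.69, the RNA sensor gene Ddx58 by -2.19 and the ubiquitin-like modifier gene Isg15 by -1.69. The chemokine genes Cxcl9 and Cxcl10 differed by -2.30 and -1.44. Usp18, which encodes a negative regulator of interferon signalling, was higher by 1.05, and Irf7 differed by 0.01. With spike-in centring the list's median was -0.01, against 1.37 for all genes. Macrophage markers had a median of 0.11, and of -0.05 under normexp. After removal of the trend with probe position, chosen after seeing the data, the interferon median was -1.35.

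Of the antigen presentation and interferon gamma list, 3 of 15 members were at least 2-fold lower, with a median of -0.41 at percentile 0.45 and a bootstrap interval over genes of -0.86 to 0.44, although spike-in centring turned it to 1.02. The immunoproteasome genes Psmb9, Psmb10 and Psmb8 differed by -2.06, -1.28 and -1.11, while the class I genes H2-K1 and H2-D1 differed by 0.44 and 0.54. The list lay at percentile 3.33 under normexp and 3.05 without a filter on dim probes.

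**Figure D2:**
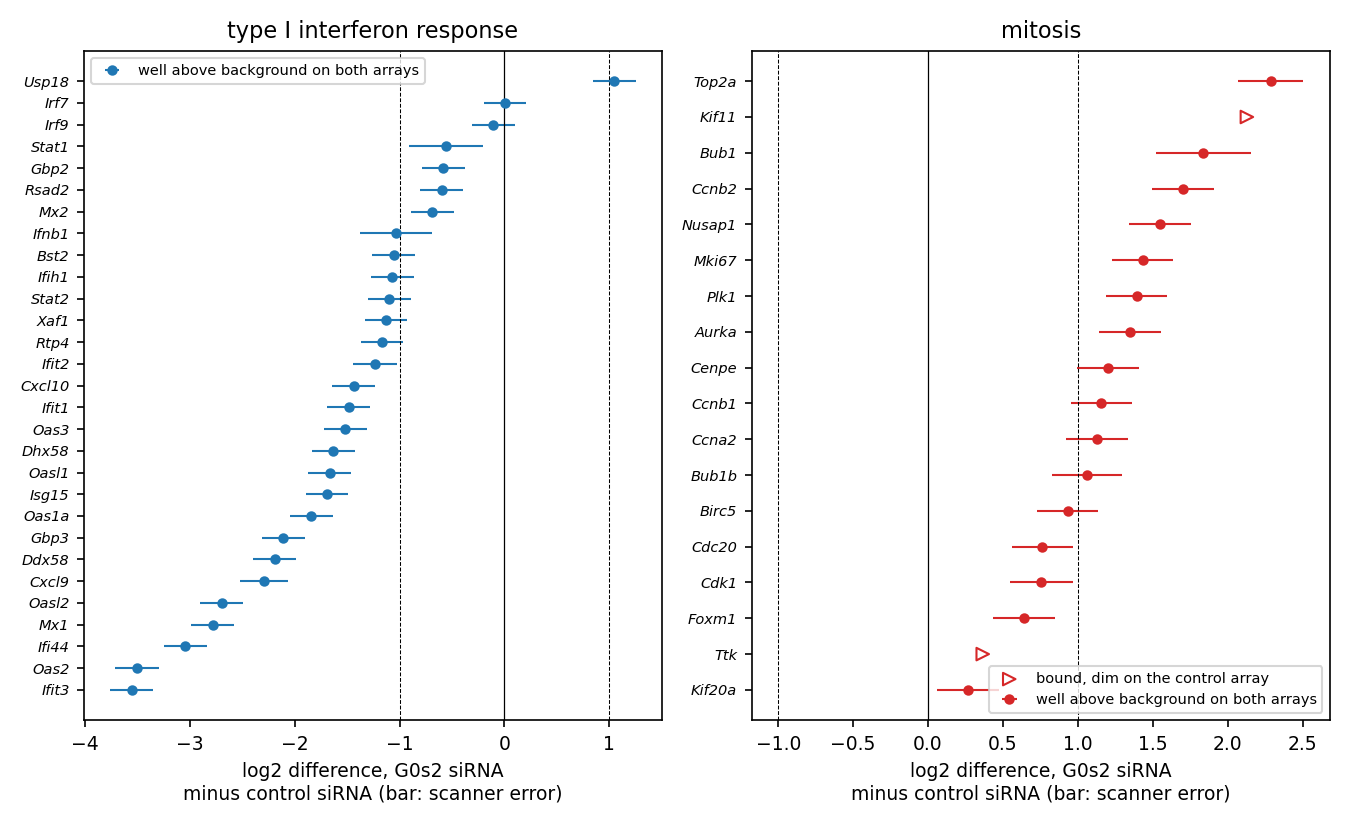
Log2 differences, G0s2 siRNA minus control siRNA, of members of the type I interferon and mitosis lists, with bars for the scanner's error and open triangles for bounds. In the interferon list 22 of 29 members lie at or beyond 2-fold lower, and in the mitosis list 12 of 18 lie at or beyond 2-fold higher.

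Mitosis genes were higher as a group. All 18 measured members of the list had a positive difference, 12 were at least 2-fold higher, and the median was 1.18, above all random lists. Members dim on the control array enter as bounds, which cannot be negative. Among probes above background on both arrays, 16 members were measured and the median was also 1.18. Top2a, a topoisomerase gene used in chromosome segregation, differed by 2.29, the checkpoint kinase gene Bub1 by 1.84, the cyclin gene Ccnb2 by 1.70 and the proliferation marker Mki67 by 1.43. Kif11 was at least 4.37-fold higher. The median after removal of the probe position trend was 1.11. Endothelial markers had a median of 0.51, and of 0.00 under normexp.

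DNA replication genes had a median of 0.22 at percentile 97.4, with 1 of 21 members at least 2-fold higher, Rrm2, a ribonucleotide reductase gene, at 1.37. That list stood apart under normexp at percentile 98.0 and among genes above background on both arrays at 98.1, but lay at 95.8 under loess and at 93.3, with a median of 0.15, after removal of the probe position trend. G1 regulators, a list that holds G0s2 itself, had a median of -0.84 at percentile 0.01, with a bootstrap interval of -1.11 to 0.27. In it 6 members were positive and 5 of 15 members were at least 2-fold lower, among them the D-type cyclin genes Ccnd1 at -1.38 and Ccnd2 at -1.35, and the cell cycle inhibitor Cdkn2b at -1.17, while Rbl1 differed by 1.13. Averaging over probes moved this median to -0.23 at percentile 9.99, and spike-in centring turned it to 0.59.

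**Figure D3:**
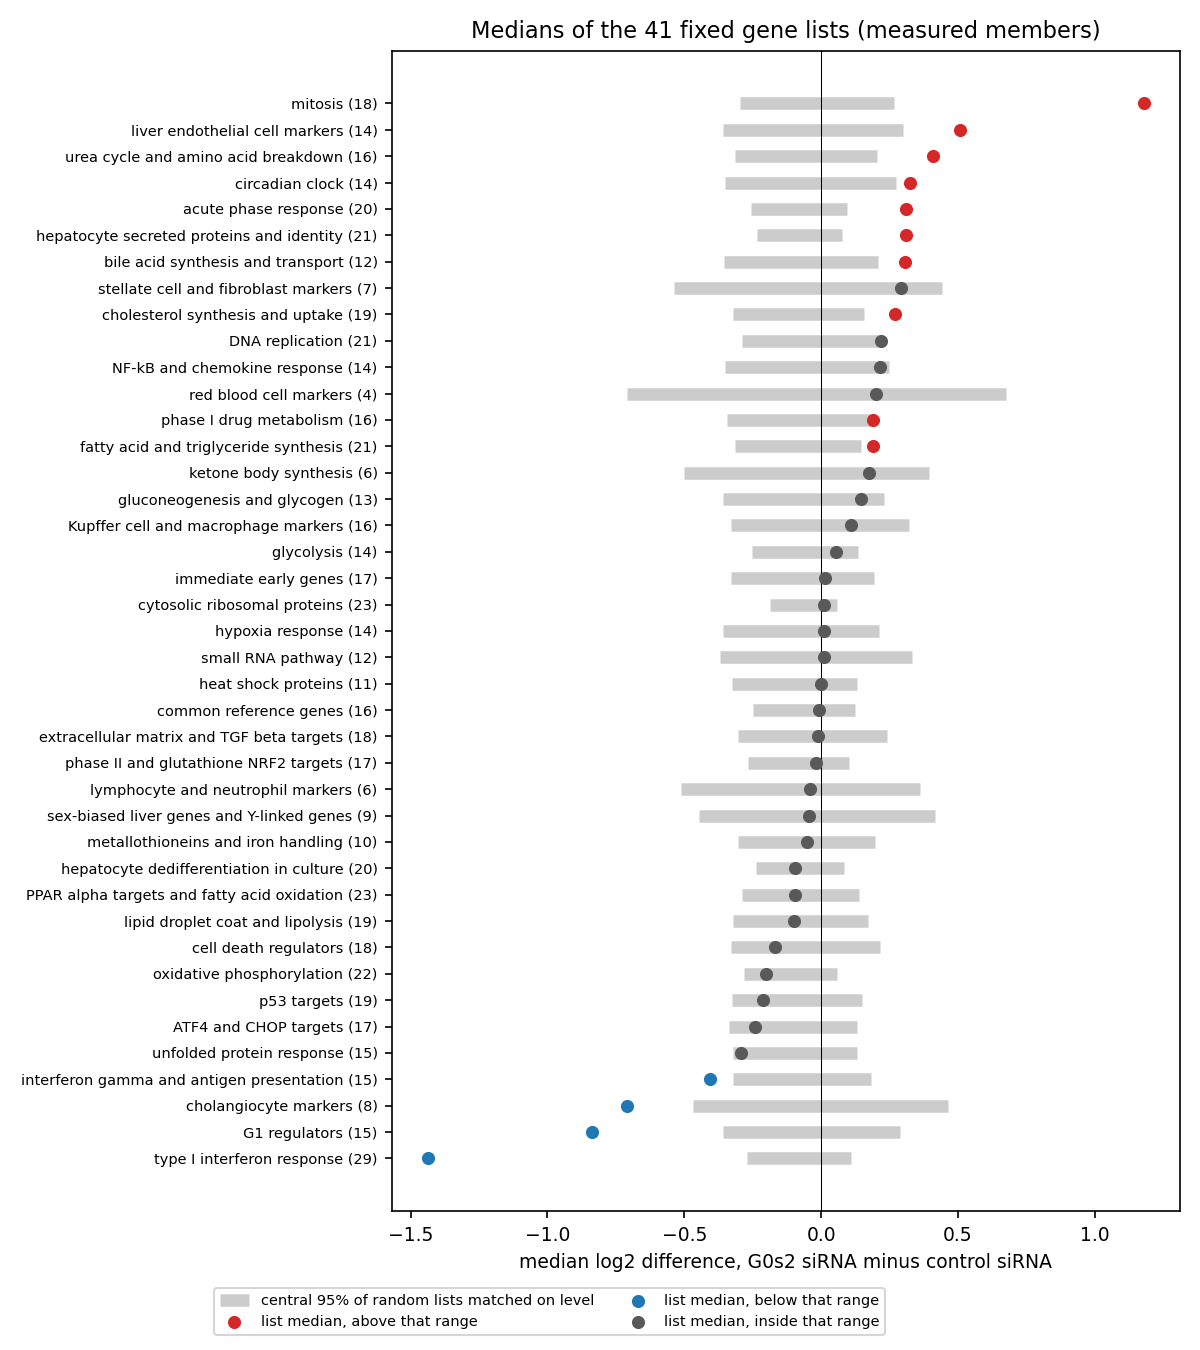
Median log2 difference, G0s2 siRNA minus control siRNA, of each of the 41 fixed gene lists, with the number of measured members in brackets and grey bars for the central 95% of random lists matched on level. There were 10 lists above their range and 4 below it. About 2.05 lists would lie outside if genes varied independently. Genes of a list can vary together and some lists share members, so that number is no measure of chance here.

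Lipid genes differed in both directions. In the fatty acid and triglyceride synthesis list, 6 of 21 members were at least 2-fold higher, 2 were at least 2-fold lower and the median was 0.19 at percentile 98.9. The desaturase gene Fads1 differed by 1.94, the triglyceride synthesis gene Dgat2 by 1.38 and the fatty acid synthase gene Fasn by 1.23, while the transcription factor gene Pparg differed by -1.99 and Thrsp by -1.66. That list was inside its range when probes were averaged, at percentile 95.8, and when random lists were matched on probe position, at 92.4. Cholesterol synthesis genes had a median of 0.27 at percentile 99.7, with Dhcr7 at 0.94. Lipid droplet and lipolysis genes lay inside their range with a median of -0.10, with 3 of 19 members at least 2-fold higher and 1 lower. The higher genes were the monoglyceride lipase gene Mgll at 1.40, Fitm2 at 1.30, whose other probe gave 0.32, and Cideb at 1.21, and the lower gene was Cidea at -1.05. Pnpla2 differed by 0.15. Fatty acid oxidation genes also lay inside, with a median of -0.10, and held Slc25a20 at 1.48 but the hormone gene Fgf21 at -2.48 and Vnn1 at -1.97. Ketone body genes lay inside with a median of 0.18, including the transporter gene Slc16a6 at 0.92, although its other probe gave -0.63.

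Several lists of hepatocyte functions had medians above random lists, mostly through differences under 2-fold. In the urea cycle and amino acid breakdown list 4 of 16 members were at least 2-fold higher and none lower, with a median of 0.41 at percentile 99.9, and Arg1, arginase, differed by 1.90 and Tdo2 by 1.29. Hepatocyte secreted protein and identity genes had a median of 0.31 with 17 of 21 members positive, 2 at least 2-fold higher and 1 lower, including Apoa4 at 1.47 and the nuclear receptor gene Hnf4a at 1.04, while the coagulation factor gene F9 differed by -1.43. Acute phase genes had a median of 0.31, with 1 of 20 at least 2-fold higher, Fga at 1.30, and 1 lower. Bile acid genes had a median of 0.31 with 0 of 12 at least 2-fold higher and 2 lower, including Abcb4 at -1.27, while Cyp27a1 differed by 0.88. Clock genes had a median of 0.32 with 0 of 14 past the rule and Per2 at 0.92. Drug metabolism genes of phase I had a median of 0.19, with 3 of 16 at least 2-fold higher, including Cyp2b10 at 1.35, and 1 lower, Cyp1a2 at -1.77. Of these lists, bootstrap intervals over genes included 0 for the acute phase median, from -0.09 to 0.51, the bile acid median, from -0.21 to 0.62, and the phase I median, from -0.13 to 0.67. The clock list lay at percentile 97.3 and the phase I list at 96.4 against random lists matched on probe position, and the clock list at 96.8 without a filter on dim probes. The phase I list, barely above its range in the main values, also lay inside it under quantile normalization at 97.3 and under both other filters on dim probes.

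The remaining pathway lists lay inside their ranges in the main values. Gluconeogenesis had a median of 0.15 with Igfbp1 at 1.67, glycolysis 0.05 with the glucose transporter gene Slc2a1 at 1.96 and the hexokinase gene Hk2 at -1.41, and phase II and glutathione genes -0.02 with the cystine transporter gene Slc7a11 at 2.56. Oxidative phosphorylation had a median of -0.20 and cytosolic ribosomal proteins 0.01. The medians were -0.29 for the unfolded protein response, with Creld2 at -1.19, and -0.24 for ATF4 and CHOP targets, with Nupr1 at -1.88. The unfolded protein response list lay below its range under normexp, quantile normalization and the mean over probes, at percentiles 2.24, 1.44 and 0.07. Heat shock proteins had a median of -0.00, p53 targets -0.21 with Ccng1 at 1.52 but Plk2 at -1.22 and Bax at -1.01, and cell death regulators -0.17 with Bak1 at -1.37 but Xiap at 1.26. Heat shock proteins stood apart upward with the mean over probes, at percentile 98.7, and cell death regulators downward under normexp, at 2.06. NF-kB and chemokine genes had a median of 0.22 at percentile 96.2, with Icam1 at 1.57 and Ccl7 at -1.95, and stood apart upward under normexp at 98.2. Medians were 0.01 for immediate early genes, 0.01 for hypoxia genes, -0.01 for matrix genes, -0.09 for dedifferentiation genes, -0.05 for metallothioneins and iron handling and 0.01 for small RNA pathway genes, in which Dicer1 differed by 1.37 and Eif2ak2 by -1.16. Common reference genes had a median of -0.01.

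Of 6 lists of markers of other cell types, 4 lay inside their ranges. Endothelial markers had a median of 0.51 at percentile 99.9, with Cdh5 at 1.01 and Flt1 at 0.94, but Kdr at -0.51, whose other probe gave 1.27. Their bootstrap interval was -0.05 to 0.76, and their median was 0.00 at percentile 95.2 under normexp. Cholangiocyte markers had a median of -0.71 at percentile 0.29, with Cldn7 at -1.29, Krt19 at -1.13 and Sox9 at -0.94, but Prom1 at a bound of 1.21, and spike-in centring turned it to 0.72. Of 8 measured markers 2 were positive, and the bootstrap interval of the median was -1.13 to 0.35. Macrophage markers, with Mpeg1 at -1.18 and Cd14 at 1.10, lay inside their range. So did stellate cell markers with a median of 0.29, although they stood apart upward at percentile 98.2 without a filter on dim probes. Lymphocyte and neutrophil markers at -0.04, red blood cell markers at 0.20, and sex-biased and Y-linked genes at -0.04 also lay inside. In the sex-biased and Y-linked list, 2 of 9 measured members were at least 2-fold higher and 0 lower, with a bootstrap interval of -0.19 to 2.03. That list mixes genes whose shifts can offset each other, so its median cannot show whether the cells on both arrays matched in sex.

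Differences were higher with increasing position of the probe in the transcript, at Spearman rho = 0.174 across 12288 genes. Position counts from the start of the transcript and is bounded by its length, and an effect of length was not separated from it. The median was -0.26 in the lowest of 10 bins of genes, with probes at positions 3 to 635, and 0.07 in the highest, from 4706 onward. All 14 lists that stood apart did so in the same direction after that trend was removed, an alternative chosen after seeing the data. Against random lists matched on probe position, also chosen after seeing the data, the lists above their range numbered 7, without the fatty acid and triglyceride synthesis, phase I and clock lists.

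**Figure D4:**
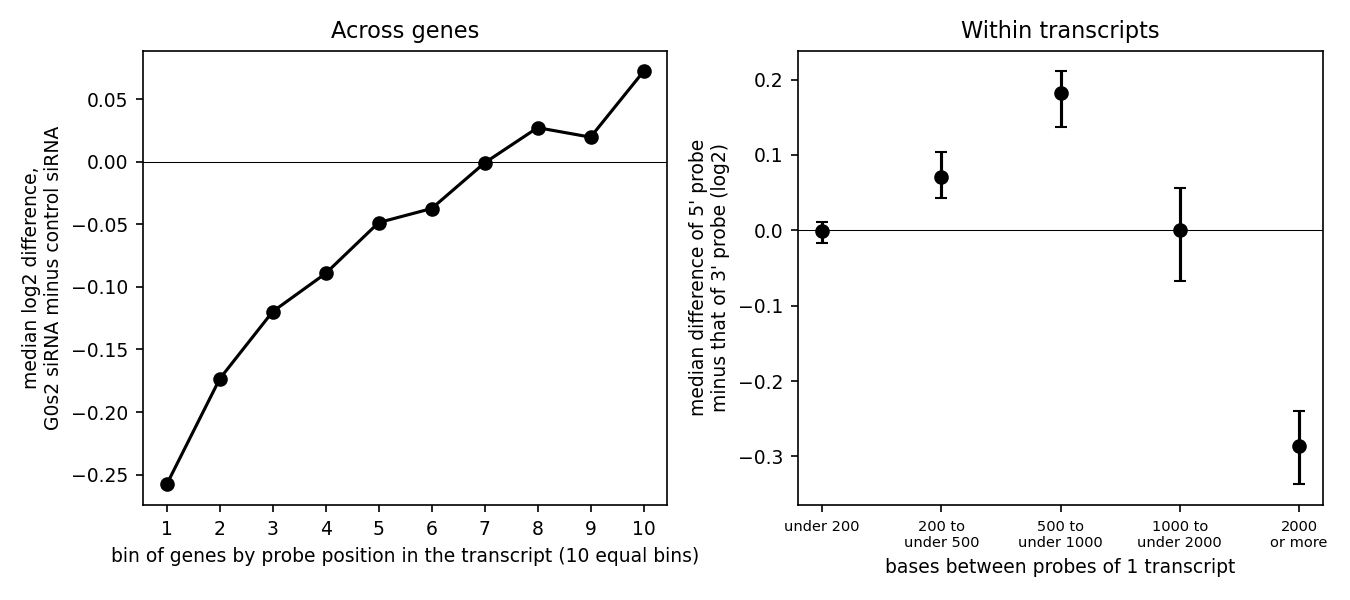
Left, median log2 difference, G0s2 siRNA minus control siRNA, over 10 equal bins of 12288 genes ordered by probe position. Right, median difference of the 5' probe minus that of the 3' probe of the same transcript by the bases between them, with bootstrap 95% intervals, which is 0.18 at 500 to under 1000 bases and -0.29 at 2000 or more.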

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

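The count in this part was chosen after the data were seen. Probes without a current gene symbol were outside the gene comparison, and 149 of the 3465 measured were at least 2-fold higher with G0s2 siRNA than with control siRNA. A further 106 were at least 2-fold lower. Among genes with a symbol, 4.8% were at least 2-fold higher and 5.5% lower, and neither share was larger among these probes.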

How the results depend on the processing

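Removal of the probe position trend, matching on probe position and the count restricted to genes with several probes were chosen after seeing the data. Compared with -2.70 in the main values, the G0s2 difference was -2.36 under normexp and -2.36 with centring on the median of probes above background, and -1.28 with spike-in centring. It stayed negative under every alternative run. Genes at least 2-fold higher and lower numbered 378 and 517 under normexp, 1647 and 375 with median centring, 12112 and 47 with spike-in centring, and 1523 and 1455 without a filter on dim probes. They numbered 1918 and 2245 by a 1.5-fold rule, 176 and 236 by a 3-fold rule, and 105 and 99 by the mean over probes among genes with several probes, where fewer genes were counted and probes were averaged. Median centring raised the median difference of all genes to 0.29 and spike-in centring to 1.37, from -0.03, and the counts follow that shift. Among the 14 lists that stood apart, medians turned sign only under spike-in centring, for interferon gamma and antigen presentation at 1.02, G1 regulators at 0.59 and cholangiocyte markers at 0.72. Medians of lists inside their ranges also turned sign under other settings, such as ketone body genes at -0.20 under normexp and -0.38 among probes above background on both arrays, and oxidative phosphorylation at 0.14 with median centring. Median and spike-in centring add 1 constant to all differences measured on both arrays, so calls against random lists are no evidence of robustness under them. The lists above their range numbered 7 to 11 and those below 3 to 5 over all settings. Of the single-gene values under alternatives, 252 moved by less than the scanner error and 92 by more, with none turning sign. Many of the 252 equal the main value by construction. These include values with saturated spots left out, both-array genes under other dim filters, and the mean over 1 probe. The genes were chosen for their large differences, so the lack of sign turns is no evidence of robustness. No spot was saturated, so leaving out saturated spots tested nothing. The cause was not tested for the other moved values. Signal over background limits dim genes, where differences are bounds for 1040 genes dim on the control array and 259 dim on the other. No paired analysis was possible because each group has 1 array.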

Other observations

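The gene families, the Ly6 neighbourhood and the single genes in this opening were chosen after their values were seen, and the tests of explanations in this part, removal of the probe position trend included, were chosen after the data were seen. The bounds for the interferon and mitosis medians after trend removal were set before those medians were computed. Among 354 families of genes sharing a symbol stem, 39 stood apart from random lists, and 30 did so in the same direction after the probe position trend was removed. If genes varied independently, 17.7 would stand apart, but members of a family can vary together, so that number is no measure of chance here. Aldo-keto reductase genes (Akr) had a median of -0.79 with 13 of 14 negative, including Akr1c19 at -1.45 and Akr1b3 at -1.10. Genes with the stem Bmp, bone morphogenetic proteins and the kinase gene Bmp2k, had a median of -0.91 with 5 of 8 negative. The CXC chemokine genes (Cxcl) had a median of -1.02 with 7 of 10 negative, including Cxcl13 at -2.61, and among them Cxcl5, Cxcl9 and Cxcl10 were already described as lower. Fatty acid elongase genes (Elovl) had a median of 0.83 with 5 of 6 positive, and some belong to fixed lists, with Elovl2 at 1.07 and Elovl1 at 1.05. Mitochondrial ribosomal genes had medians of -0.42 for Mrps and -0.33 for Mrpl, with 1 of 30 and 2 of 49 at least 2-fold lower. The Mrpl median was -0.21, inside its range at percentile 4.41, after the trend was removed. Such small shifts were not limited to these families. The stem Ndufa had a median of -0.39 with 15 of 15 negative, and Cox -0.32 with 19 of 24 negative. After trend removal Ndufa lay at percentile 0.51, and Cox inside its range at 6.24.

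In the Ly6 region of chromosome 15, 7 of 25 neighbouring genes were at least 2-fold lower, and this window had the lowest median of any, -0.60. In it Ly6a differed by -2.44 and Ly6c1 by -2.29. The highest window median was 0.45, and no random reference for the lowest of many windows is given here. Outside the fixed lists, 2 cytokine genes that act on macrophages were lower on the G0s2 siRNA array, Csf1 at -2.60 and Il34 at -2.37, as was the endothelin gene Edn1 at -2.77. The growth factor gene Nrg4 was higher at 2.43, with its other probe at 1.81.

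Interferon genes were lower with G0s2 siRNA. A trend with probe position and GC content did not account for this, since the median was -1.35 after its removal, outside the random range of -0.25 to 0.13. Fewer macrophages as the whole cause were argued against by macrophage markers, with a median of 0.11 and an interval of -0.16 to 0.56. The interferon median was -1.44. Under normexp the macrophage median was -0.05 and the interferon median -1.30. That interval resamples genes of 1 array per group, so the values do not settle whether fewer macrophages were the cause. Whether the control siRNA raised interferon genes or G0s2 siRNA lowered them cannot be told apart, because the series as analysed here has 0 arrays of cells without siRNA. A lower interferon response after loss of G0s2 may be one explanation and stays untested.

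Mitosis genes were higher with G0s2 siRNA, with a median after removal of the trend of 1.11, outside the random range of -0.29 to 0.25. A larger share of endothelial cells as the whole cause was argued against by a mitosis median 0.67 above the endothelial median. The interval over genes was 0.31 to 1.32. This holds only if both lists would rise by about as much, which was not tested. Entry into the cell cycle after loss of G0s2 may be an explanation, but DNA replication genes, at 0.22 against a random range up to 0.22 and at percentile 93.3 after removal of the trend, left it open. Genes with the symbol stem Mcm, a family chosen after its values were seen that shares members with the replication list, had a median of 0.47 at percentile 99.4 with 9 of 10 positive, which does not settle it. A few dividing cells of any type were not tested for.

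Differences were higher with increasing probe position across genes. Stronger loss of 5' sequence on the control array was argued against by probe pairs over 2000 bases apart, where the 5' minus 3' difference was -0.29, with an interval of -0.34 to -0.24. That value has the direction that stronger loss on the G0s2 siRNA array would give. Such loss at every separation was argued against by pairs 500 to under 1000 bases apart, at 0.18 with an interval of 0.14 to 0.21. Neither alone could account for both. Transcript length, which bounds the position a probe can have, was not separated from position, and no biological explanation was tested.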
